A study of Mus musculus with 2 samples.

How the data were processed

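Single-cell RNA sequencing with a droplet-based 10x Genomics 3' kit was done on Treg cells sorted from mouse spleen. There were 2 libraries, Foxp3YFP-Cre Kmt2d+/+ (here +/+) and Foxp3YFP-Cre Kmt2dfl/fl (here fl/fl), each made from the pooled cells of 3 mice. Each group has 1 library, so no test across replicates could be made. The submitters' processing notes name fastp, Cell Ranger 7.1.0 and Seurat 4.1.1, with the genome builds mm10 and GRCm38. The deposited matrices hold raw counts of unique molecular identifiers (UMIs) per gene and barcode for 31253 genes, with no normalization, and were checked to hold whole numbers only. The cell filters behind the deposited barcodes are not stated in the labels.

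The +/+ file held 7947 barcodes and 53680614 UMIs, and the fl/fl file 8784 barcodes and 63989234 UMIs. Barcodes with fewer than 500 genes (70 and 95) or more than 10% mitochondrial counts (124 and 110) were left out, which left 7790 and 8634. Doublets were scored within each library by the method of Scrublet, written anew in Python with an expected doublet rate of 6%. Its automatic threshold called 0.0770% and 0.0927% of barcodes, under the 0.5% below which a caller was taken not to have worked. The threshold was therefore set by Otsu's method on the simulated doublet scores, a choice made after that output was seen. It called 211 (2.71%) and 209 (2.42%) barcodes, which were left out, leaving 7579 and 8425 single cells.

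Both libraries were clustered together on log-normalized counts, with 2000 variable genes ranked within each library, 30 principal components, 15 nearest neighbours and Leiden resolution 1.0. Among the genes kept out of the variable genes were 644 that differed at least 1.5-fold between the sums of the 2 libraries. T cell receptor and immunoglobulin segments and mitochondrial, ribosomal and sex-linked genes were kept out as well. This gave 29 clusters. Clusters were named "-like" from 19 marker lists fixed before the data were examined, as were the gene lists, the filters, the comparisons and most of the alternatives. A class was open to a cluster when at least 3 of its markers, its first 2 included, reached 20 CPM (UMI counts scaled so that every library or cluster has the same total), and the open class with the highest mean marker z-score was taken. Another class with at least 3, and more, markers among the 10 genes of highest fold took its place. The scoring rule and its 20 CPM level were set after the data were seen, and the rule was revised 2 times after its output was seen. All 3 versions were run, and the effector share depends on the version.

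Clusters named as a class other than a T cell were left out, and unnamed T cell clusters stayed in. The resulting T cell population held 13 clusters, with 6337 +/+ cells (39851571 UMIs) and 6440 fl/fl cells (45671192 UMIs). Of these clusters, 5 were Treg-like (0, 1, 2, 6 and 9) and 2 were conventional CD4 T cell-like (3 and 4).

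Counts were summed per library and scaled to CPM by total UMIs. For each gene the log2 ratio of CPM, fl/fl over +/+, was given with a 95% exact conditional binomial interval, and single sums with an exact Poisson interval. Genes at 10 CPM or more in either library counted as measured. Numbers of genes with a CPM ratio of at least 1.5, either way, with an interval excluding 1, follow a rule of size and are not numbers of genes found changed by a test. Shares of cells have 95% exact binomial (Clopper-Pearson) intervals. Shares of cells with a UMI were taken after thinning each cell to 2500 UMIs, which left out 111 +/+ and 96 fl/fl shallower cells. A share of 0 is given with its exact binomial upper limit.

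There were 26 gene lists, and each one's median log2 ratio was set beside those of 10000 random lists of the same size, matched on mean expression in 20 bins. The 95% range of a median comes from 1000 Poisson draws of the counts. Named genes followed a fixed rule. They are the 12 highest and 12 lowest CPM ratios among genes at 20 CPM or more with an interval excluding 1 and the same direction in all cells past the filters, in cells with a Foxp3 UMI and in thinned cells. Receptor and immunoglobulin segments, mitochondrial, ribosomal protein and sex-linked genes and gene models without a proper symbol were left out of these. To them were added Kmt2d, P2rx7 and Foxp3 and up to 4 members of each list, those with the largest ratios each way. The rule gave 115 genes, and any other gene is said to have been chosen after its values were seen.

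The alternatives were scaling by the median of gene-wise ratios, all deposited barcodes, non-T clusters kept, only cells with a Foxp3 UMI, doublets kept, thinned cells, clusters weighted alike, other CPM floors and folds, Leiden resolutions 0.5 and 1.5, the differing genes kept for clustering, and a mitochondrial limit of 5%. Only the Treg-like clusters, Treg-like clusters weighted alike, and the other naming rules were added after the data were seen.

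The calling of genes and lists was tested on simulated data with 200 changed genes and 200 unchanged lists of 20 genes per comparison. Counts were drawn as Poisson counts from the +/+ library's shares, the model that the intervals assume. No variation between cells, mice, sorts or libraries was simulated. The results therefore check the calling under counting error only, and say nothing of how often such differences arise between real libraries. In the T cell population (7920 genes) 100% of the 2-fold and 100% of the 3-fold changed genes were called, and 0 of 7720 unchanged genes. In Treg-like cells (7857 genes) the shares were 99% and 100%, with 0 of 7658 unchanged genes called. In conventional CD4 T cell-like cells (7768 genes) they were 100% and 99%, but 52 of 7569 unchanged genes were called. In Treg-like and in conventional CD4 T cell-like cells, but not in the T cell population, a changed gene fell below the CPM floor in the simulated counts. It was left out of the genes given. The intervals held the true ratio of 95.4%, 94.6% and 94.9% of the unchanged genes. Of the unchanged lists 4%, 4.5% and 7% fell outside the middle 95% of random lists.

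Coordinates were taken from GENCODE M21 on GRCm38. The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scikit-image 0.26.0, igraph 0.11.9, leidenalg 0.10.2, statsmodels 0.14.6 and matplotlib 3.10.9.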

Results

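Splenic CD4+Foxp3+ Treg cells, the T cells that hold immune responses in check, were compared between mice with intact Kmt2d and mice with a floxed Kmt2d, both carrying Cre recombinase with a yellow fluorescent protein at the Foxp3 locus. Kmt2d encodes a histone H3 lysine 4 methyltransferase. There was 1 library per genotype, each a pool of 3 mice, with no replicates, so values are given side by side as a description of these libraries. The intervals cover counting error only. The deposited +/+ matrix held a median of 5562 UMIs and 2124 genes per barcode, and the fl/fl matrix 6039.5 and 2142. After filtering, T cells made up 83.6% of the +/+ and 76.4% of the fl/fl single cells, although both samples had been sorted for Treg cells.

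Kmt2d (ENSMUSG00000048154, GRCm38 chromosome 15, 98831669 to 98871204, minus strand), the targeted gene, was at 71.3 CPM in the +/+ and 66.3 CPM in the fl/fl T cell population, a log2 ratio of -0.10 (-0.18 to -0.03). In Treg-like cells it was at 74.7 and 72.8 CPM (-0.04, -0.13 to 0.05), and in conventional CD4 T cell-like cells at 80.5 and 64.7 CPM (-0.32, -0.51 to -0.12), while over cells with a Foxp3 UMI the ratio was 0.055. It was lower in B cell-like clusters 5 (-0.51, -0.88 to -0.13), 10 (-0.58, -1.12 to -0.03) and 12 (-0.52, -0.95 to -0.10), while the interval of cluster 23 (-0.13) included 0. CD8 T cell-like cluster 8 was at -0.36 (-0.67 to -0.04) and cluster 14 at 0.11 (-0.54 to 0.80). Why Kmt2d was lower in some cells other than Treg-like ones was not tested. The labels do not say which exons were floxed. Tags near the 3' end come from outside a deletion elsewhere in the gene, so these levels check nothing about it. Foxp3 (ENSMUSG00000039521, chromosome X, 7573644 to 7595245, plus strand), the transcription factor that defines Treg cells and the gene the sort rested on, was at 26.4 CPM in +/+ and 19.0 CPM in fl/fl T cells (-0.48, -0.61 to -0.34). Within Treg-like cells it was at 36.8 and 28.3 CPM (-0.38, -0.52 to -0.24). It was lower in clusters 0 (-0.78) and 1 (-0.57), while the intervals of clusters 2 (0.01), 6 (-0.43) and 9 (0.12) included 0. Both groups carry the YFP-Cre insertion in the 3' part of Foxp3, and the labels do not say whether the reference held its sequence, so Foxp3 tags can be undercounted in both libraries. After thinning, 6.59% of +/+ and 4.68% of fl/fl T cells held a Foxp3 UMI (13.7% and 11.2% unthinned, at median depths of 5510 and 6222 UMIs). The thinned share was 8.73% and 7.11% in Treg-like cells. It was 0.335% of +/+ conventional CD4 T cell-like cells and 0 of 1229 fl/fl ones, which allows up to 0.300%. B cell-like cells, which should lack Foxp3, gave 0.191% and 0.0811% (1.32% and 0.386% unthinned, at median depths of 5004.5 and 4400 UMIs).

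P2rx7, which encodes the ATP-gated channel P2X7 named in the series title, was lower in fl/fl Treg-like cells. P2rx7 (ENSMUSG00000029468, chromosome 5, 122643911 to 122691432, plus strand) was at 71.7 CPM in +/+ and 39.7 CPM in fl/fl Treg-like cells, 1.81 times lower (log2 ratio -0.86, -0.97 to -0.75). It was lower in each of the 5 Treg-like clusters, with log2 ratios of -1.19 in cluster 0, -0.83 in cluster 1, -1.06 in cluster 2, -0.51 in cluster 6 and -0.80 in cluster 9. Interferon-responding (-0.85) and cycling (-0.88) T cell-like clusters also had less P2rx7 in the fl/fl library. These clusters can hold Treg cells, by their level of the Treg marker Ikzf2, chosen after its values were seen. Ikzf2 was at 1393 CPM in +/+ and 1808 CPM in fl/fl interferon-responding cells, and at 1115 and 1653 CPM in cycling ones. In conventional cluster 3 it was at 55.6 and 48.6 CPM, and in conventional cluster 4 at 421.0 and 331.6 CPM. The lower level was not seen in conventional CD4 T cell-like cells, at 30.2 and 38.3 CPM (0.34, 0.05 to 0.63), nor in CD8 T cell-like cells, at 14.2 and 15.1 CPM (0.09, -0.54 to 0.72). Of the CD8 T cell-like clusters, cluster 8 was at 12.7 and 9.35 CPM (-0.44, -1.30 to 0.40), an interval that takes in the Treg-like ratio. Cluster 14 was at 21.6 and 28.4 CPM (0.39, -0.68 to 1.59). Within the conventional class, cluster 3 was at 7.48 and 5.74 CPM (-0.38, -1.34 to 0.56) and cluster 4 at 62.7 and 68.8 CPM (0.13, -0.18 to 0.45). Cluster 4 made up 39.6% of the +/+ and 46.6% of the fl/fl class, and at Leiden resolution 1.5 the class ratio was -0.042. Over the whole T cell population P2rx7 was at 61.7 and 39.1 CPM (-0.66, -0.75 to -0.57), from 2458 and 1785 counts. A P2rx7 UMI was found in 13.1% of +/+ and 8.89% of fl/fl thinned T cells (26.6% and 19.9% unthinned), and in 14.9% and 9.10% of Treg-like cells. The thinned share was 6.03% and 7.24% in conventional CD4 T cell-like cells, and 1.34% and 0.730% in B cell-like cells (3.21% and 1.85% unthinned).

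**Figure D1:**
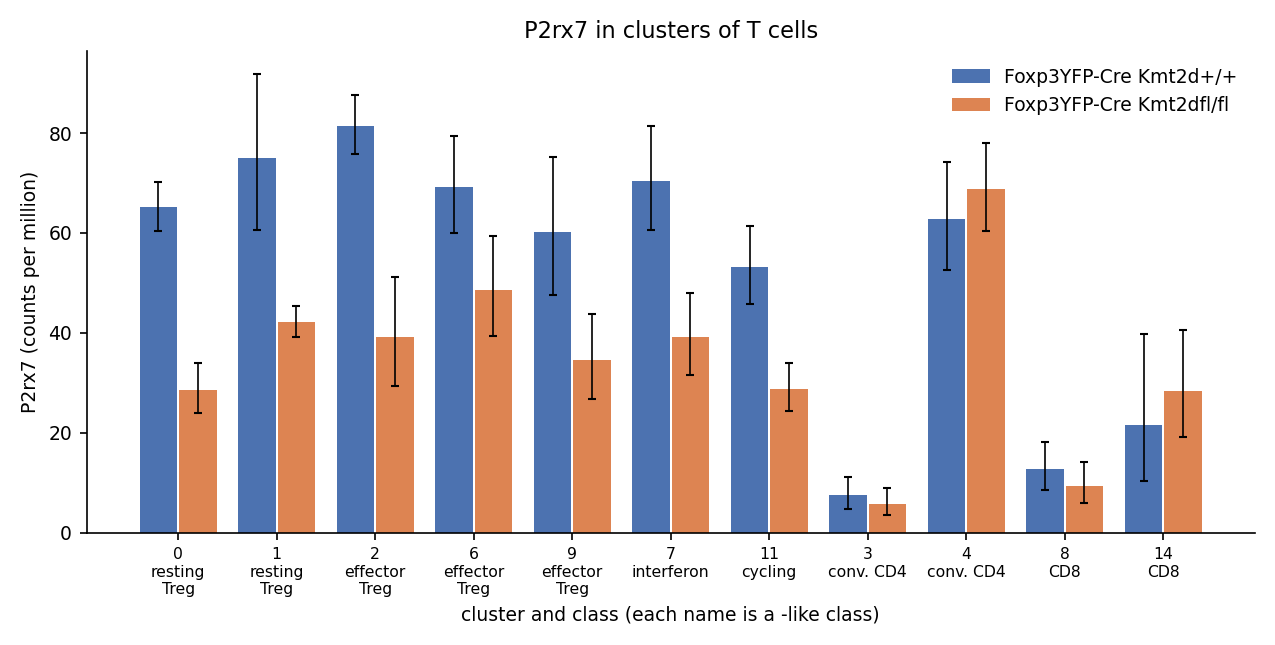
P2rx7 in CPM (vertical axis) per T cell cluster, named by number and class (horizontal axis), in the +/+ and fl/fl libraries; bars are summed counts and error bars exact 95% Poisson intervals. In each of the 5 Treg-like clusters the fl/fl bar is lower, as in cluster 0 with 65.1 against 28.6, while in conventional cluster 4 the bars stand at 62.7 and 68.8.

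Over the T cell population, genes at a lower level in the fl/fl library outnumbered those at a higher level. Of 8006 measured genes 134 had a CPM ratio of at least 1.5 and 443 were as far below, and at 2-fold the numbers were 55 and 147. In cells with a Foxp3 UMI 271 were higher and 889 lower by 1.5-fold. The lower genes were 76.8% of those past 1.5-fold, and 63.7% (331 against 189 higher) when the libraries were scaled by the median of gene-wise ratios. The median log2 ratio of all measured genes was -0.09 in the T cell population and -0.14 in Treg-like cells, which is the level other ratios should be read against. Among the 12 highest named genes were Pard3b, Tspoap1, Plac8, Gzmb, Socs2, Cpq, Peli2, Nrn1, Zfp608, Ccl4 and Eomes. Pard3b, a cell polarity gene, was at 3.69 CPM in +/+ and 47.3 CPM in fl/fl T cells (log2 ratio 3.68, 3.44 to 3.93). Plac8 was at 48.7 and 309.8 CPM (2.67, 2.60 to 2.74). Gzmb, the cytotoxic protease granzyme B, was at 14.96 and 51.2 CPM (1.78, 1.64 to 1.91). Socs2, a feedback inhibitor of cytokine signalling, was at 23.2 and 61.5 CPM (1.41, 1.30 to 1.52). The 12 lowest were Camp, S100a8, S100a9, Ngp, Ryr2, Apobec3, Nav2, Tshz2, Neurl3, Slc15a2, Cybb and Cd83. Ryr2, a calcium release channel, was at 32.2 and 3.57 CPM (-3.17, -3.42 to -2.94). Apobec3, a cytidine deaminase that restricts retroviruses, was at 151.5 and 21.1 CPM (-2.85, -2.95 to -2.75). Cd83, a surface marker of activated lymphocytes, was at 85.2 and 23.03 CPM (-1.89, -1.99 to -1.79). Camp, S100a8, S100a9 and Ngp are neutrophil genes, with log2 ratios from -4.70 to -4.22. Of the 10792 neutrophil marker counts in the +/+ T cell population 89.6% lay in 13 cells, and the fl/fl population held 556 such counts. Ccl4 had 972 counts in the +/+ and 2744 in the fl/fl T cell population, of which 39 and 1064 lay in conventional CD4 T cell-like and 798 and 1258 in CD8 T cell-like cells. Eomes had 343 and 943, of which 22 and 199 lay in Treg-like, 71 and 265 in cycling and 197 and 335 in CD8 T cell-like cells.

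The lists of Treg identity and suppressive effector genes had medians below those of all 10000 random lists in the T cell population. Of 28 measured Treg identity genes 1 was at least 1.5-fold higher, 12 as far lower and 15 neither (median log2 ratio -0.44, percentile 0 among random lists). Socs2 was the higher one. Within resting Treg-like cells this list had 5 of 24 higher and 7 lower, and its median of -0.13 (percentile 19.6) was not apart from random lists, while within effector ones it was -0.26 (percentile 0.02). Tnfrsf4, the costimulatory receptor OX40, was at 205.9 and 96.2 CPM (-1.10), while Il2ra, the high-affinity interleukin-2 receptor chain, was at 228.5 and 296.4 CPM (0.38). Il2ra turned to -0.12 with the clusters weighted alike. Among 16 suppressive effector genes 2 were higher (Gzmb and Fgl2) and 8 lower (median -0.46, percentile 0). They included Ebi3, a subunit of interleukin-35, at 11.5 and 1.18 CPM (-3.28), and Entpd1, the ectoenzyme CD39 that breaks down ATP, at 23.8 and 10.3 CPM (-1.21). The 13 purinergic genes had 2 higher, 5 lower and 6 neither (median -0.26, percentile 1.54). Their median was 0.062 (percentile 96.1) within resting and -0.30 (percentile 1.2) within effector Treg-like cells. The lower ones besides P2rx7 and Entpd1 included Adora2a, an adenosine receptor (-1.36), and Adk, adenosine kinase (-1.44), and the higher ones were the receptor genes P2ry14 (1.23) and P2ry10b (0.94).

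The list of resting (central) Treg genes stood above random lists and that of effector (activated) Treg genes below. Of 20 resting Treg genes 1 was at least 1.5-fold higher and 4 lower, with a median of 0.30 (percentile 100), and by a ratio of at least 5 to 4 there were 9 higher and 6 lower. Igfbp4 (1.00) and Klf2, a transcription factor of quiescence and recirculation (0.53), were higher. Ly6c1 (-1.33) and Il6ra, an interleukin-6 receptor chain (-1.22), were lower. Of 29 effector Treg genes 1 was higher and 7 lower (median -0.33, percentile 0), with the chemokine receptor genes Ccr8 at -2.16 and Ccr2 at 0.80. The summed effector Treg markers were at 2422 CPM in +/+ and 1849 CPM in fl/fl T cells. Follicular Treg genes had 4 of 10 lower and 0 higher (median -0.37, percentile 0.1), among them Tox2 (-1.86) and Il1r2, a decoy receptor for interleukin-1 (-1.46). Within resting Treg-like cells the follicular median was 0.25 (percentile 99.4) with 1 of 7 higher and 0 lower, and within effector ones -0.75 (percentile 0). T helper-like genes had 2 of 9 lower and 0 higher (median -0.26, percentile 3.83), with Il1rl1, the interleukin-33 receptor, at 14.4 and 0.766 CPM (-4.24). Homing and chemokine receptor genes had 3 of 20 higher and 7 lower (median -0.15, percentile 11.3). Their median was -0.51 (percentile 0.01) in Treg-like cells, -0.19 (percentile 13.4) within resting and 0.16 (percentile 99.8) within effector ones.

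The medians of the TCR, NF-kB and immediate-early lists were below those of nearly all random lists, though few members passed 1.5-fold. The 30 TCR signalling genes had 0 higher and 2 lower, Egr2 (-0.83) and Ptpn6 (-0.81), with a median of -0.29 (percentile 0). The 20 NF-kB and TNF receptor genes had 0 higher and 5 lower (median -0.30, percentile 0.02), with Tnfrsf1b, the TNF receptor abundant on Treg cells, at -0.96. The 26 immediate-early and dissociation stress genes had 0 higher and 5 lower (median -0.31, percentile 0), led by Dusp1 (-0.96) and Zfp36 (-0.87), although Cd69 (0.32) and Jun (0.30) were higher. IL-2 and STAT5 genes had 1 of 15 higher and 2 lower (median -0.01, percentile 88.5). Their median was -0.13 (percentile 20.3) within resting and -0.26 (percentile 0.82) within effector Treg-like cells. Of the 20 cell death genes 1, the p53 target Bbc3 (0.71), was higher and 1, Casp4 (-0.60), lower (median -0.01, percentile 96.1). Survival genes had 0 of 14 higher and 3 lower (median -0.07, percentile 53.5), with Bcl2 at 0.52 and Bcl2l1 at -0.71. Interferon response genes had 1 of 30 higher, Iigp1 (0.75), and 1 lower, Ifi208 (-1.73), with a median of 0.04 (percentile 99.96) that turned to -0.10 in cells with a Foxp3 UMI. The 27 cell cycle genes had 0 past 1.5-fold either way but a median of 0.18 (percentile 100), in a population whose share of cycling cells differed, and in Treg-like cells the 12 measured ones had a median of 0.010 (percentile 89.0).

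Few chromatin and metabolic genes reached 1.5-fold. None of 18 genes of H3K4 methyltransferase complexes and H3K27 demethylases reached 1.5-fold (median -0.12, percentile 27.3), and the largest ratio was that of the demethylase gene Kdm6b (-0.58). Of 21 other chromatin regulators 1, Hdac7 (-0.63), was lower (median -0.11, percentile 26.6). Hdac7 lies near Kmt2d (chromosome 15, 97792664 to 97844502), so a difference carried along with the floxed allele cannot be told apart for it. In conventional CD4 T cell-like cells no gene of this list was 1.5-fold lower. No member reached 1.5-fold either way among 17 glycolysis (median -0.05, percentile 78.2), 28 oxidative phosphorylation (-0.04, 81.4), 14 cholesterol synthesis (-0.08, 65.2), 12 MHC class I (-0.00, 79.9), 13 mitochondrially encoded (-0.21, 1.19), 4 nuclear-retained RNA (-0.10, 31.2), 2 sex-linked (-0.05, 50.9) and 15 housekeeping genes (0.00, 80.5). The medians of oxidative phosphorylation, cholesterol synthesis, survival and sex-linked genes turned positive when scaled by the median of gene-wise ratios.

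**Figure D2:**
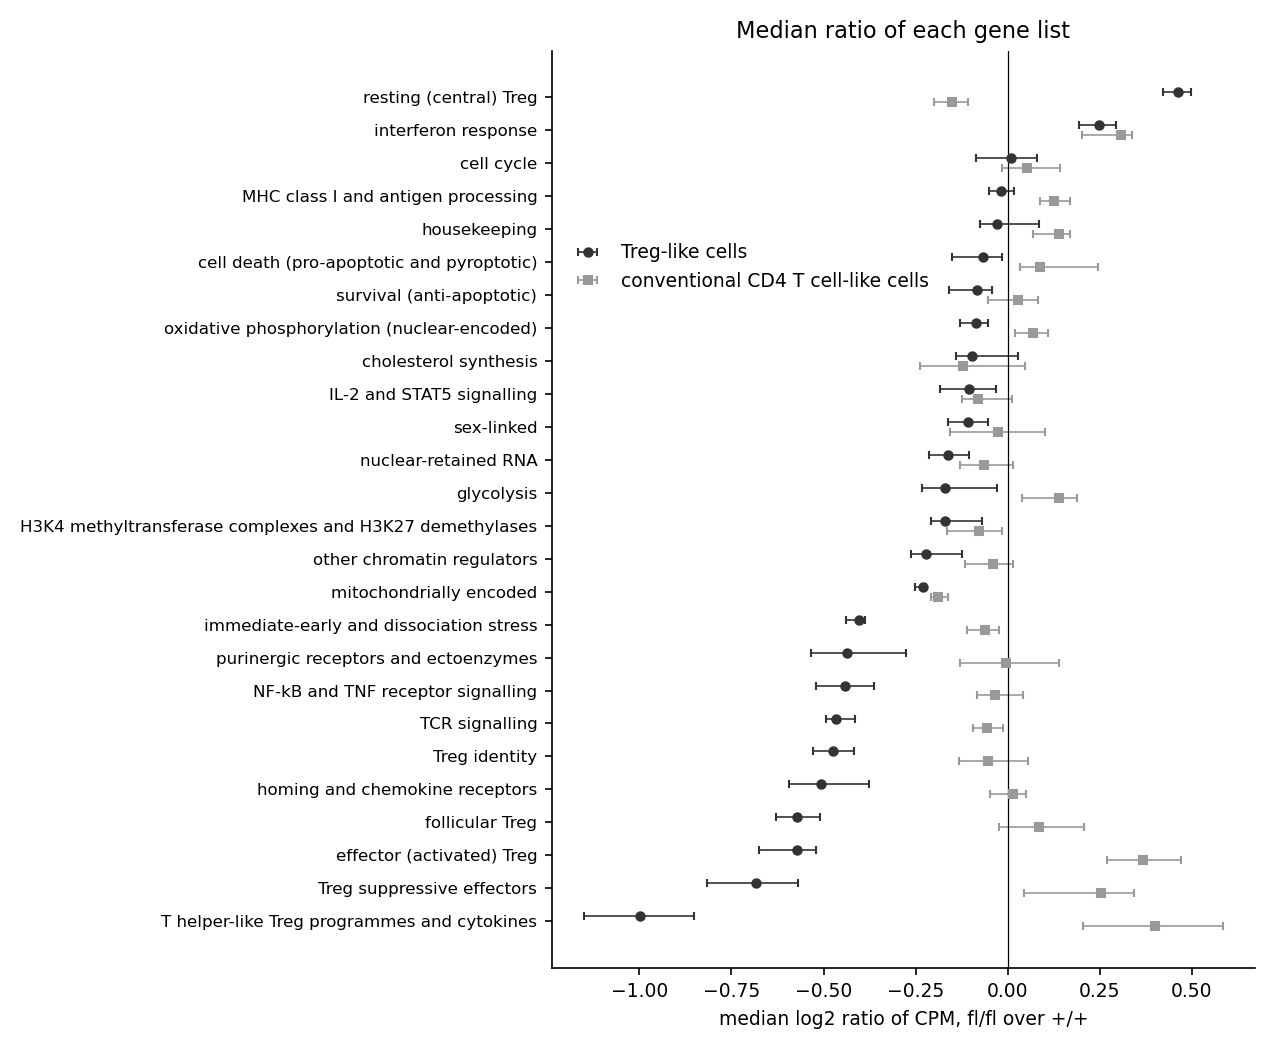
Median log2 ratio of CPM, fl/fl over +/+ (horizontal axis), for each gene list (vertical axis) in Treg-like and conventional CD4 T cell-like cells; points are medians over the measured members and error bars 95% ranges over 1000 Poisson draws of the counts. In Treg-like cells the effector (activated) Treg list lies at -0.57 and the resting list at 0.46, while in conventional cells they lie at 0.37 and -0.15.

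The fl/fl library held more resting Treg-like cells, and its Treg-like cells lay largely in another cluster than those of the +/+ library. Resting Treg-like cells were 32.1% (31.0 to 33.3) of the +/+ and 47.8% (46.6 to 49.1) of the fl/fl T cell population. Of Treg-like cells, cluster 0 held 42.6% in +/+ and 21.4% in fl/fl, cluster 1 held 4.38% and 58.7%, cluster 2 held 34.9% and 4.34%, cluster 6 held 12.2% and 7.17%, and cluster 9 held 5.93% and 8.47%. Clusters 1 and 2 were mostly of 1 library each, and with 1 library per group such a cluster may be that library and not a cell type. Effector Treg-like cells (clusters 2, 6 and 9) were 36.3% (35.1 to 37.5) of the +/+ and 11.9% (11.2 to 12.8) of the fl/fl T cell population. This share rests on the naming rule. Under its first version cluster 2 was named follicular Treg-like and cluster 6 was unnamed, and the effector share was 4.04% in +/+ and 5.18% in fl/fl. With the differing genes kept for clustering it was 13.4% and 10.8%. The resting share was higher in the fl/fl library under each of 8 alternatives, by 13.6 to 18.2 points. The Treg-like clusters (0, 1, 2, 6 and 9) together were 68.4% of the +/+ and 59.8% of the fl/fl T cells. Interferon-responding cells (cluster 7) were 6.88% and 5.51%, and cycling cells (cluster 11) 2.87% and 4.55%. Clusters 7 and 11 held Ikzf2, a Treg marker, far above the conventional clusters, so Treg cells can lie outside the Treg-like share. Conventional CD4 T cell-like cells were 14.2% and 19.2%, and CD8 T cell-like cells (clusters 8 and 14) 5.96% and 8.35%. The sort for CD4+Foxp3+ cells, and how pure each sort was, can set these last shares.

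**Figure D3:**
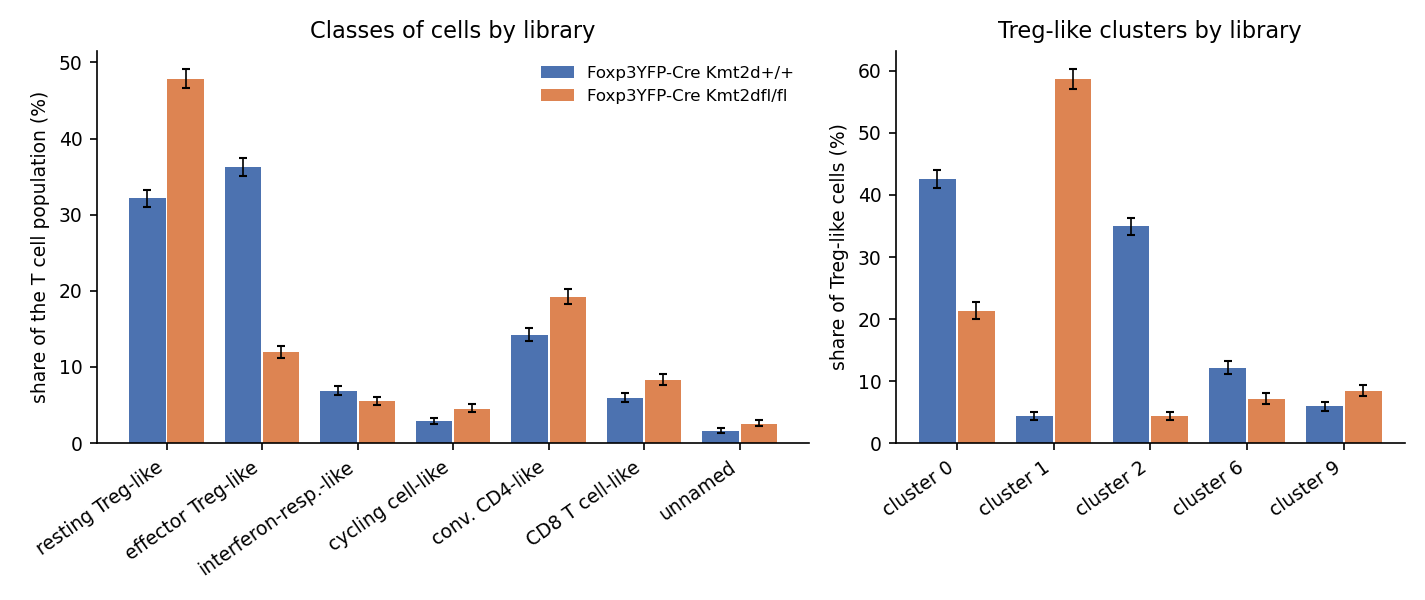
Share of cells in percent (vertical axis) per class or cluster (horizontal axis) in the +/+ and fl/fl libraries; bars are shares and error bars exact 95% binomial intervals. Resting Treg-like cells stand at 32.1% and 47.8%, and cluster 1 at 4.38% and 58.7% of Treg-like cells.

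Within Treg-like cells alone the differences were wider than over all T cells, with 199 of 7950 measured genes at least 1.5-fold higher and 813 as far lower. With the 5 clusters weighted alike the numbers were 195 and 627 of 7941. Resting Treg-like cells, of which cluster 0 held most in +/+ and cluster 1 most in fl/fl, had 264 higher and 607 lower. Effector Treg-like cells, of which cluster 2 held most in +/+ and cluster 9 the largest part in fl/fl, had 392 and 761. Resting cells held 11805252 UMIs in +/+ and 21759567 in fl/fl, and effector ones 13310660 and 5276921. Counting error is thus larger for the effector numbers, which should not be set against the resting ones. Plac8 was at 16.8 and 321.0 CPM in Treg-like cells (4.26, 4.11 to 4.40) and Pard3b at 4.26 and 70.6 CPM (4.05, 3.77 to 4.35). Ebi3 was at 14.8 CPM in +/+ and 0.111 CPM in fl/fl Treg-like cells (-7.06, -9.34 to -5.50, from 3 fl/fl counts). Il1rl1 (-4.97), Tox2 (-3.89), Neurl3 (-3.34), Tshz2 (-3.07) and Nav2 (-3.01) were lower too, although within resting Treg-like cells the intervals of Tox2 and Nav2 included 0. Of the 20 resting Treg genes 8 were higher and 5 lower (median 0.46, percentile 100), including Bcl2, a survival factor (0.67), and Satb1, a chromatin organizer (0.61). Within resting Treg-like cells the list had 1 higher and 6 lower (median 0.076), and within effector ones 5 of 18 higher and 4 lower (median 0.28). Bcl2 was at 0.39 in resting and -0.34 in effector Treg-like cells, and Satb1 at -0.0021 and 0.87. These values also hold a different mix of clusters within each state. Bcl2 was at 0.29 in resting cluster 0 and at -0.26 in resting cluster 1. In effector clusters 2 (0.13) and 9 (0.92) Bcl2 was higher, and in cluster 6 (-0.04) its interval included 0. Of 28 effector Treg genes 1 was higher and 14 lower (median -0.57, percentile 0). Within effector Treg-like cells alone that list's median was 0.25, and within resting ones -0.24. T helper-like genes had 0 of 8 higher and 5 lower (median -0.999, percentile 0), with Ifng, the gene of interferon-gamma, at 26.2 and 7.102 CPM (-1.89). The median of the T helper-like genes was -0.16 (percentile 37.7, 4 measured genes) within resting and -0.58 (percentile 0.01) within effector Treg-like cells. Within resting cells the Ifng interval included 0, and within effector ones Ifng was at -0.86. Suppressive effector genes had 2 of 16 higher and 8 lower (median -0.68, percentile 0), with Entpd1 at -1.77 and Gzmb at 2.51. Within resting Treg-like cells that list's median was 0.22 (percentile 99.89) and within effector ones -0.23 (percentile 1.85). NF-kB and TNF receptor genes had 7 of 19 lower and 0 higher (median -0.44, percentile 0.01). Interferon response genes had 5 of 29 higher and 1 lower (median 0.25, percentile 100). Ribosomal protein genes took 25.8% of the +/+ and 31.2% of the fl/fl UMIs of Treg-like cells, and mitochondrial genes 3.05% and 2.55%. The ribosomal share was 29.4% and 32.9% within resting and 22.6% and 24.3% within effector ones, so a part of the difference goes with the mix of states. It was 28.2% and 28.6% in conventional CD4 T cell-like and 23.3% and 25.6% in B cell-like cells. In Treg-like cells the summed neutrophil markers were at 159.2 and 12.6 CPM, and 81.5% of the 3999 +/+ counts lay in 5 cells. Markers of cytotoxic cells were higher in the fl/fl Treg-like cells, as Gzmb was, with summed NK cell markers at 7.80 and 25.4 CPM (1.70) and CD8 T cell markers at 105.4 and 142.5 CPM (0.44).

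Conventional CD4 T cell-like cells, in which Foxp3 is largely silent, showed about as many higher as lower genes, 143 and 135 of 7833 at 1.5-fold, but 47 and 19 at 2-fold. In simulated data of this size 52 of 7569 unchanged genes were counted, so a part of these numbers is of the size that counting error gives. Treg-like cells thinned to the UMIs of the conventional ones had 234 higher and 940 lower. Of the 7554 genes measured in both, 164 thinned Treg-like and 101 conventional genes were higher and 25 were shared, where independent lists of these sizes would share 2.2. Lower were 790 and 107, with 50 shared where such lists would share 11.2. In both classes Apobec3 (-2.92 in Treg-like, -2.34 in conventional cells), Slc15a2, a peptide transporter (-1.88 and -1.75), and Ifi208 (-1.82 and -0.90) were lower, and Iigp1 (0.99 and 0.90) and Ccr2 (1.03 and 1.23) higher. Of 26 effector Treg genes in conventional cells 9 were higher, 0 lower and 17 neither (median 0.37, percentile 100). T helper-like genes had 4 of 11 higher and 0 lower (median 0.40, percentile 100), with Ifng at 86.9 and 133.6 CPM (0.62), and suppressive effector genes 2 of 11 higher (median 0.25, percentile 99.98). Of 29 interferon response genes 3 were higher and 1 lower (median 0.31, percentile 100). Resting Treg genes had 0 of 20 higher and 1 lower (median -0.15, percentile 0.13). These list values also hold a different mix of clusters. Cluster 4, with Ifng among its leading genes, made up 39.6% of the +/+ and 46.6% of the fl/fl class. The lists were not taken within each conventional cluster. Ccl4 (4.38), Gzmb (2.59) and Eomes (1.60) were higher in the fl/fl class, as were the summed CD8 T cell markers, at 549.2 and 1728 CPM (1.65). Of the 3467 erythroid marker counts in the fl/fl class 98.2% lay in 1 cell. The difference between the classes was not tested.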

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

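All tests of the patterns below were chosen after the result was seen, except those of the pools or sorts, of genes near Kmt2d and of free RNA.

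P2rx7 was lower in fl/fl Treg-like cells. A technical difference across the whole library would lower it in other cells too. The log2 ratio in conventional CD4 T cell-like cells was 0.34 (0.05 to 0.63), above the interval of Treg-like cells. It was -0.042 at a higher Leiden resolution. In cluster 4 of that class, where P2rx7 is abundant, the ratio was 0.13 (-0.18 to 0.45). These values argue against a difference that acts alike on all cells, but not against one that acts more on some. The intervals of conventional cluster 3 (-0.38, -1.34 to 0.56) and CD8 T cell-like cluster 8 (-0.44, -1.30 to 0.40) take in the Treg-like ratio. Those clusters cannot decide. P2rx7 was lower in myeloid cell-like cluster 19 (-2.62, -5.75 to -0.60) but not in cluster 15 (0.63, -0.03 to 1.28). A different mix of clusters is argued against by the ratio with the Treg-like clusters weighted alike, -0.93 (-1.09 to -0.77). More cells of another type inside the fl/fl Treg-like clusters would lower other Treg genes by about as much, but the summed Ikzf2 and Ctla4 ratio was 0.056 (0.04 to 0.07), that of the 10 Treg markers -0.11 and that of Foxp3 -0.38, which argues against such cells as the whole explanation but, with the median of Treg identity genes at -0.47, not as a part of it. The Kmt2d genotype remains open and may account for the pattern, but so may any other difference between the pools, since there was 1 library per group.

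The resting share of Treg-like cells was higher and the effector share lower in the fl/fl library. For the effector share the naming rule is a possible explanation, since under its first version the difference was 1.14 points the other way, while the resting share stayed higher by at least 16.9 points under the other naming rules. A shift of the whole library that acts alike on all cells would unmix all classes alike. The share of nearest neighbours from the other library, over that by chance, was 0.912 in conventional CD4 T cell-like and 0.303 in Treg-like cells, a ratio of 3.01. This argues against a shift of that kind only. A technical shift that acts more on Treg-like cells would give the same values, so the ratio cannot decide about it. A difference between the pools of mice or their sorts other than Kmt2d cannot be told apart from genotype, because there was 1 library per group and the pool, the sort and the genotype are the same split. The genotype itself is open and untested.

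Among 6954 genes measured in Treg-like, conventional CD4, CD8 and B cell-like cells (clusters 5, 10 and 12), 12 differed at least 1.5-fold the same way in all 4 classes, 2 higher and 10 lower; those outside the naming rule, such as Lancl1, St8sia6, Cdk5rap1 and Rell1, were chosen after their values were seen. Genes carried along with the floxed allele are argued against for most of them, since 91.7% (61.5 to 99.8), 11 genes, lay on other chromosomes than Kmt2d. For Apobec3 (chromosome 15, 79891659 to 79915906) this cannot be told apart from a response to genotype. Within 20 Mb of Kmt2d lay 8.33% of the 12 genes, which is 1 gene, against 1.88% of 6951 tested genes with coordinates. The odds ratio of 4.76 runs from 0.11 to 33.2, so it cannot decide the question. Free RNA of other cells cannot be told apart either. Of these 12 genes 66.7% (34.9 to 90.1), 8 genes, were highest in another class, and the interval takes in both answers. The other classes also included T cell clusters, so this share cannot decide the question. Ifi208 and Iigp1 were highest in interferon-responding T cell-like cells, and Cdk5rap1 in the unnamed T cell clusters. S100a9 was highest in neutrophil-like cells. Of the summed neutrophil marker counts in +/+ Treg-like cells 81.5% lay in 5 cells, so few cells can set its ratio there. Apobec3 was highest in dendritic cell-like cells and stood at 376.0 and 25.3 CPM in the B cell-like clusters. A difference in strain background away from chromosome 15 was not tested, and genotype remains open.

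For 10 named genes the log2 ratios in Treg-like and conventional CD4 T cell-like cells pointed opposite ways, each by a ratio of at least 5 to 4 and with an interval excluding 0, and the difference was not tested. All 10 were lower in Treg-like cells, while named genes that missed 5 to 4 in the conventional class went either way, such as Bcl2 (0.67 and -0.22), Satb1 (0.61 and -0.19) and Hif1a (-0.48 and 0.26). The Treg-like minus conventional difference was -3.37 for Cybb, an oxidase subunit (-2.80 and 0.57), -1.20 for P2rx7, -8.53 for Ebi3 (-7.06 and 1.47), -1.51 for Casp4, an inflammatory caspase (-0.95 and 0.57), and -2.25 for Bcl2a1d, a survival gene (-1.64 and 0.61). It was -1.64 for Tnfrsf4 (-1.25 and 0.39), -2.51 for Ifng (-1.89 and 0.62), -1.44 for Tbx21, the T helper 1 regulator (-1.04 and 0.40), -3.44 for Il1r2 (-1.83 and 1.61) and -1.97 for Egr2 (-1.29 and 0.68). Over all Treg-like cells these ratios also hold the different mix of states. Within the states Casp4 was at 0.89 (0.53 to 1.26) in resting and -0.19 in effector Treg-like cells, and Tbx21 at 0.64 (-0.57 to 2.01) and 0.05 (-0.37 to 0.46), so neither was lower in both. Cybb (-1.97), Ifng (-0.86), Il1r2 (-0.64) and Egr2 (-0.97) were lower in effector Treg-like cells, while their intervals in resting ones included 0. P2rx7, Bcl2a1d and Tnfrsf4 were lower in both states. The ratios of the conventional class also hold a mix, as cluster 4 made up 39.6% of it in +/+ and 46.6% in fl/fl. For P2rx7 the intervals of conventional clusters 3 (-0.38, -1.34 to 0.56) and 4 (0.13, -0.18 to 0.45) included 0. The P2rx7 ratio of the conventional class turned to -0.042 at Leiden resolution 1.5, so its opposite direction may come from the mix. The other genes were not taken by conventional cluster.

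Clusters 5, 10 and 12 (B cell-like) and 17 and 25 (plasma cell-like), which lie outside the T cell population of the main comparisons, gave a signal in a sample sorted for Treg cells. Cluster 5 was 7.29% of the fl/fl and 3.51% of the +/+ single cells, cluster 10 was 4.70% and 1.504%, and cluster 12 was 2.85% and 1.83%. Cluster 17 was 1.44% and 0.528%, and cluster 25 was 0.404% and 0.0792%. How pure each sort was can set these shares, and the difference was not tested.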

How the results depend on the processing

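The Treg-like clusters only, these clusters weighted alike, and the other naming rules were chosen as alternatives after the data were seen. No paired analysis was possible because each group has only replicate 1. The Foxp3 ratio (-0.55 to -0.38) and its share of cells with a UMI kept their direction within counting error under the alternatives that do not select cells by Foxp3. In cells with a Foxp3 UMI the ratio was -0.36, but that choice keeps every Foxp3 count and so tests nothing about it. P2rx7 stayed lower in T cells, from -0.99 to -0.55, and in Treg-like cells, from -0.93 to -0.85. For single genes and list medians 517 of 1104 values were within counting error of the reported one, 573 moved without turning and 14 turned.

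Genes higher and lower numbered 386 and 1254 at a ratio of at least 5 to 4, 55 and 147 at 2-fold, 41 and 141 at 50 CPM or more, and 592 and 1690 with no CPM floor, as the looser or stricter rules imply. In cells with a Foxp3 UMI they numbered 271 and 889, the Kmt2d ratio turned to 0.055, P2rx7 was at -0.99, Ifng turned to -1.81 and Tbx21 to -0.91, and the interferon response median turned to -0.10. With the Treg-like clusters only, 813 genes were lower, P2rx7 was at -0.86, its share of cells with a UMI differed by -5.84 points, and Ifng (-1.89) and Tbx21 (-1.04) turned. Kmt2d was at -0.20 with all deposited barcodes and at -0.20 with non-T clusters kept. With thinned cells P2rx7 was at -0.55 and Xist turned to -0.0062. With clusters weighted alike Il2ra turned to -0.12, Tbx21 to -0.022, Tsix to 0.0052 and the sex-linked median to 0.078. Scaled by the median of gene-wise ratios, Kmt2d was at -0.015 and P2rx7 at -0.57, and the medians of cholesterol synthesis (0.0088), oxidative phosphorylation (0.049), sex-linked (0.038) and survival genes (0.020) turned. The P2rx7 share differed by -6.68 points when not thinned.

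The share of effector Treg-like cells differed by -22.8 points with doublets kept, -21.7 at 5% mitochondrial counts, -2.64 with the differing genes kept for clustering, -26.4 under the second naming rule and 1.14, the other way, under the first, which named cluster 2 follicular. The share of resting Treg-like cells differed by 13.6 points with doublets kept, 13.8 at 5% mitochondrial counts and 18.2 under the second naming rule. The P2rx7 ratio in conventional CD4 T cell-like cells turned to -0.042 at Leiden resolution 1.5. Apart from the fold and floor rules and the naming rule, the cause was not tested. Depth limits what can be said of P2rx7 in CD8 T cell-like cells, where the interval ran from -0.54 to 0.72.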

Other observations

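No test was run for these observations, and all values were looked at after the data were seen. Other cells in the sorted samples differed in share too. Myeloid cell-like cells were 3.31% of the +/+ and 1.83% of the fl/fl single cells, neutrophil-like cells 1.58% and 0.843%, NK cell-like cells 2.22% and 2.48%, dendritic cell-like cells 0.844% and 0.795%, and erythroid cell-like cells 0.831% and 0.392%. Of the CD8 T cell-like clusters, cluster 8 held 3.83% and 3.87% and cluster 14 held 1.16% and 2.52%. Cluster 16 was left unnamed. Among its leading genes were Zbtb16, Il4 and Xcl1, chosen after their values were seen, and P2rx7 was at 154.5 CPM in its +/+ and 201.4 CPM in its fl/fl cells (0.38, -0.01 to 0.78).

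Malat1, a nuclear RNA, was at 9453 CPM in +/+ and 6459 CPM in fl/fl Treg-like cells (-0.55), and at 9992 and 9614 CPM in conventional CD4 T cell-like cells (-0.06). Eef1a1, a translation factor, was at 5209 and 8202 CPM in Treg-like cells (0.65), but was not 1.5-fold higher within resting or within effector ones. Xist was found in both libraries, at 1201 and 1246 CPM in T cells. No Y-linked gene of the sex-linked list reached the CPM floor.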
